A study of Mus musculus with 4 samples.

How the data were processed

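Gene expression was measured in total RNA of 4 mouse cell samples, MEF, NSC, iNSC_13F and iNSC_14F, on Affymetrix mouse arrays with a biotin label, per the labels' protocols. The samples were grouped by their cell type labels, which gave 4 groups of 1 array. The source label names embryonic stem cells for all 4 samples, which differs from the cell type label, and it was not used. NSC and induced cells were grown in N2 medium with EGF, bFGF and laminin, per the labels' protocols. How the fibroblasts were grown is not given in the sources used here.

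The deposited values are array intensities, one linear signal per probe set. The submitters' processing notes name MAS5, a method that summarises the probes of a probe set on each array alone, and its version and settings are not given in the sources used here. The deposited intensities had a 2% trimmed mean of 500 on each of the 4 arrays, so no further scaling was applied. MAS5 scales each array by 1 factor, so differences that grow with brightness stay in the values. Detection calls were not used here, and the floor was set from the data instead.

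The 45101 probe sets held 64 controls. Probe sets were named through the platform annotation and, by gene ID, a table of the GRCm38.p6 assembly used for names and for neighbouring genes. One gene was named for 34945 probe sets, of which 34754 were matched by ID. There were 932 with several genes and 9211 with none, and neither was named. This gave 18193 genes, 9010 of them with several probe sets. A gene took the values of its brightest probe set by mean log2 signal over the arrays. The floor was the 95th percentile of 86 probe sets for odorant, vomeronasal and taste receptors, genes not thought to be expressed in these cells, taken on each array. The highest of the 4 values, 103.91, was used for all arrays. Values below it were set to it before taking log2. The 95th percentile itself was 103.9 for MEF, 37.1 for NSC, 99.4 for iNSC_13F and 70.9 for iNSC_14F. How precise a value is depends on its signal over background and on the number of arrays, which was 1 per group.

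All 6 pairs of arrays were compared. With 1 array per group there are no residual degrees of freedom, so no test was run. Genes were called by a fixed rule of size, at least 4-fold with the brighter array above the floor. Genes 4-fold apart between NSC and MEF were classed on each induced array as within 2-fold of NSC, within 2-fold of MEF, between or outside. For each of 34 gene lists, which cover cell types, position in the body, signalling pathways and cell states, members above the floor on at least 1 array of a pair counted as measured. Members at least 2-fold apart were counted. The median log2 difference was placed among 10000 random lists of the same size, matched on mean expression, where at least 3 members were measured. That percentile describes these arrays and is no test. The lists held 525 different genes, of which 486 had a probe set. They, the comparisons and the alternatives were fixed before the data were examined.

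Named genes followed a rule fixed at that time. In comparisons between NSC and MEF, of each induced array with NSC, and between the induced arrays, these were the 10 genes with the largest difference each way above the floor on both arrays and the 5 largest bounds each way. In comparisons with MEF of the induced arrays, these were 5 and 3. For genes apart from both references, the 10 with the largest smallest difference each way were taken. For each list, up to 4 members with the largest differences were taken. All members of the set of 8 factors, of the sex-linked list and of the housekeeping list could be named. Genes without an established symbol were counted but not named. Genes whose induced samples lay on opposite sides of a reference, and members of another hypoxia list of 25 genes, were named after the data were seen.

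The rule of size was tested on simulated data for 18193 genes, 2 arrays and the noise of the induced pair. It called 0.83% of genes changed 2-fold, 98.3% of those changed 8-fold and 100.0% of those changed 16-fold, with 36.65 unchanged genes called on average and 0 in the wrong direction. The changed genes were drawn only from genes well above the floor, so these shares do not hold for dimmer genes or for bounds. Simulated lists of 15 genes with no shift lay above the 95th percentile in 4.0% of 200 runs. These lists were random draws of the same genes, so this checks the calculation alone and not lists of genes regulated together. Overlaps between comparisons that share an array were set beside 100 simulations with no effect. This noise comes from 2 different samples, so it is a yardstick and not a replicate error.

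Alternatives were quantile normalization, a floor at the 75th or 99th percentile, no floor with a pseudocount of 16, the median of a gene's probe sets, leaving out probe sets with the suffix _s_at or _x_at, and keeping only genes above the floor on both arrays of a pair (all 4 for results over 4 arrays). Scaling to the hybridization controls, and leaving out the NSC or the MEF array from the genes apart from both references, were added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The order of genes in the annotation was used only to find neighbouring genes. Probe sequences were not used here.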

Results

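Total RNA from 4 mouse cell populations was measured on 1-colour Affymetrix arrays, with 1 array for each population. The populations were mouse embryonic fibroblasts (MEF), primary-derived neural stem cells (NSC), and induced neural stem cells made with 13 factors (iNSC_13F) or with 14 factors (iNSC_14F). Induced neural stem cells are cells of another lineage that have been turned towards a neural stem cell state by introduced factors. The series concerns adult liver cells and B lymphocytes as starting cells, but the starting cell of each induced sample is not given in the labels. Because each group has 1 array, no difference reported here has a replicate check, and no SD or p-value is given. The number of arrays limits the precision of every value. Of 18193 genes with a probe set, 10561 were above the floor on the MEF array, 9854 on the NSC array, 10164 on the iNSC_13F array and 9956 on the iNSC_14F array. The floor was a signal of 103.91, and a fold against an array at or below it is a lower bound, written "at least". The NSC array stood apart in its hybridization controls, bacterial and phage transcripts added to each sample, whose amounts are not given in the sources used here. They were 1.88-fold lower on it than on the MEF array, 2.11-fold lower than on iNSC_13F and 1.91-fold lower than on iNSC_14F. The poly-A controls, another set of bacterial transcripts, were also lowest on NSC, by 2.12-fold, 3.47-fold and 2.43-fold against the same arrays. So was the highest signal, at 37965 on NSC against 66957, 67418 and 73179. The 99th percentile was 13647 on NSC against 17084, 18962 and 18852. Scaling to the hybridization controls applies 1 factor to all signals of an array, so it cannot follow a difference that varies with brightness. The ratio of 3' to 5' signal of the actin control was 1.42 for MEF, 1.35 for NSC, 1.53 for iNSC_13F and 1.65 for iNSC_14F. That of the Gapdh control lay between 0.723 and 0.806.

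The profiles were first compared as wholes, to ask whether the induced cells lay nearer to neural stem cells or to fibroblasts. Across 12320 genes above the floor on at least 1 array, the induced arrays correlated more closely with each other than with either reference, at a Pearson r of 0.964 (Spearman rho 0.948). The r of iNSC_13F was 0.807 with NSC and 0.764 with MEF, and that of iNSC_14F was 0.831 with NSC and 0.766 with MEF. NSC and MEF correlated at 0.748. These are correlations across genes, which are not independent replicates. The nearness to NSC rested on genes below the floor on some array. Over the 8154 genes above the floor on all 4 arrays, r with NSC minus r with MEF was -0.0191 for iNSC_13F and 0.0057 for iNSC_14F, against 0.0428 and 0.0655 over the wider set. The difference between the 2 induced arrays served as a yardstick for all others, although it holds real differences as well as noise. Among genes above the floor on both, 95% differed by less than 2.32-fold.

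The NSC and MEF arrays were compared to define the reference difference between neural stem cells and fibroblasts. Genes of neural stem cells and radial glia were far higher in NSC. Of 28 measured members of that list, 24 were at least 2-fold higher and 1 was at least 2-fold lower, with a median log2 difference of 3.59. Fabp7, a fatty acid binding protein of radial glia, was 177-fold higher, and Olig1, a transcription factor of neural progenitors, was at least 209-fold higher. Bcan, a proteoglycan of the neural extracellular matrix, was at least 111-fold higher and Olig2 at least 82.7-fold higher. Sparcl1 (57.6-fold), Map2 (36.0-fold), Car2 (35.8-fold), Sema6d (32.6-fold) and Aldoc (30.8-fold) were among the genes with the largest differences. All probe sets of Map2 (4), Sema6d (2) and Aldoc (2) went that way, but the smallest log2 differences were 0.13, 0.46 and 1.00. The floor limits the difference of a dim probe set. Gpm6a, Gpm6b and Bex2 were higher by at least 145-fold, at least 144-fold and at least 137-fold. Fibroblast genes were lower in the same comparison. Of 38 measured members of the fibroblast and mesenchyme list, 36 were at least 2-fold lower in NSC and 0 were higher, with a median log2 difference of -6.25. Igfbp7 was 235-fold lower, Fn1, which encodes fibronectin, 157-fold lower and Anxa1 124-fold lower. The collagen genes Col1a2 and Col3a1 were at least 497-fold and at least 375-fold lower. In all, 700 genes were at least 4-fold higher in NSC and 828 were at least 4-fold lower, so that 45.8% of the calls were higher. When the arrays were scaled to their hybridization controls, 79.4% were higher, the median of all genes moved from -0.01 to 0.82 (log2), and that of the neural stem cell list to 4.39. Over genes above the floor on both arrays the medians of the neural stem cell and fibroblast lists were 2.57 and -3.96.

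Other gene groups also separated NSC from MEF. Genes of cholesterol synthesis were higher in NSC, with 13 of 15 measured members at least 2-fold higher and a median log2 difference of 1.47. Idi1 was 7.84-fold, Dhcr7 6.21-fold and Hmgcs1 3.94-fold higher. Genes that feed back on ERK signalling had a median of 1.24, with 7 of 13 higher and 2 lower. Spry4 (9.72-fold) and Etv5 (9.38-fold) were higher, while Dusp5 was 10.5-fold lower. Of 31 cell cycle genes 12 were higher and 0 lower (median 0.80), led by Kif11 (9.71-fold) and Nusap1 (8.63-fold). In the other direction, 13 of 16 genes of glycolysis and hypoxia were at least 2-fold lower in NSC, with a median log2 difference of -2.39. P4ha2 was at least 52.5-fold lower and the glucose transporter gene Slc2a1 was 11.5-fold lower. Genes of the unfolded protein response were also lower (9 of 14, median -1.86), among them Ddit3 (13.8-fold) and Trib3 (9.59-fold). So were genes of the BMP response (6 of 7, median -2.18), among them Smad6 (at least 12.8-fold) and Smad7 (at least 12.6-fold). The Hox genes of paralog groups 6 to 13, which mark posterior position along the body axis, had a median of -2.06, with 12 of 14 lower. All 14 of these were bounds. All 7 medians kept their sign under both other scalings, but with scaling to hybridization controls each moved upwards by about 0.9 except that of the Hox genes, all of which are bounds. Under that scaling those of cholesterol synthesis, ERK feedback and the cell cycle were 2.38, 2.15 and 1.67. Those of glycolysis and hypoxia, the unfolded protein response and the BMP response were -1.49, -0.95 and -1.27.

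The induced cells were set against MEF to ask how far they lay from fibroblasts. The neural stem cell and radial glia genes were higher on both induced arrays. In iNSC_13F 21 of 25 measured members were at least 2-fold higher and 0 lower, with a median log2 difference of 3.95. In iNSC_14F the counts were 22 of 26 and 0, and the median was 3.96. Olig1 was at least 333-fold higher in iNSC_13F and at least 383-fold higher in iNSC_14F. Bcan was higher by at least 294-fold and at least 226-fold, and Fabp7 by 117-fold and 145-fold. Aldoc, an aldolase found in astrocytes and radial glia, was 117-fold higher in iNSC_13F and 193-fold higher in iNSC_14F. Sox3 was 33.4-fold higher in iNSC_13F, and Fgfr3 was 45.5-fold higher in iNSC_14F. Fibroblast genes were lower, with 34 of 38 at least 2-fold lower in iNSC_13F (median -5.52) and 35 of 38 in iNSC_14F (median -5.78). Col1a2 was 446-fold and 450-fold lower, and Tpm2 was 310-fold and 223-fold lower. The smooth muscle actin gene Acta2 was 205-fold lower in iNSC_13F and 120-fold lower in iNSC_14F. Counts at 4-fold were 431 genes higher and 1091 lower for iNSC_13F, and 520 higher and 929 lower for iNSC_14F. Over genes above the floor on both arrays they were 240 and 640, and 287 and 513. With no floor 680 genes were higher in iNSC_13F.

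Several of the gene groups that separated NSC from MEF did so in the induced cells as well. Cholesterol synthesis genes were at least 2-fold higher than in MEF for 13 of 15 members in iNSC_13F (median 1.58) and 14 of 15 in iNSC_14F (median 1.67). Dhcr7, the last enzyme of the pathway, was higher by 8.45-fold and 13.2-fold. The ERK feedback genes had medians of 1.28 and 1.54, with 7 of 13 higher and 1 lower in iNSC_13F and 8 higher and 2 lower in iNSC_14F, and Etv5 higher by 25.0-fold and 19.6-fold. The unfolded protein response genes had medians of -1.07 (7 of 14 lower) and -1.20 (9 of 14), with 0 higher. Those of the BMP response had -1.31 and -1.35, with 4 of 7 lower on each array and 1 higher in iNSC_13F. Trib3 was 9.79-fold lower in iNSC_13F. Posterior Hox genes had medians of -1.56 and -2.05, with bounds for 12 and 15 of 15 members, and Hoxd13 was at least 19.8-fold lower on both arrays. The Wnt response list had a median of 0.46 in iNSC_13F and 1.21 in iNSC_14F over 7 measured members, but the latter was -0.18 with a lower floor. Nkd1 was at least 8.84-fold higher in iNSC_14F, with 2 of its 3 probe sets in that direction. The comparisons of the induced arrays with MEF share the MEF array. They had 322 genes higher in both and 826 lower in both, where independent lists would share 19.8 and 89.6, and simulated arrays with no effect shared 11.1. The log2 differences had a covariance of 1.87, against 0.139 in the simulation. Part of this excess may come from the shared array.

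**Figure D1:**
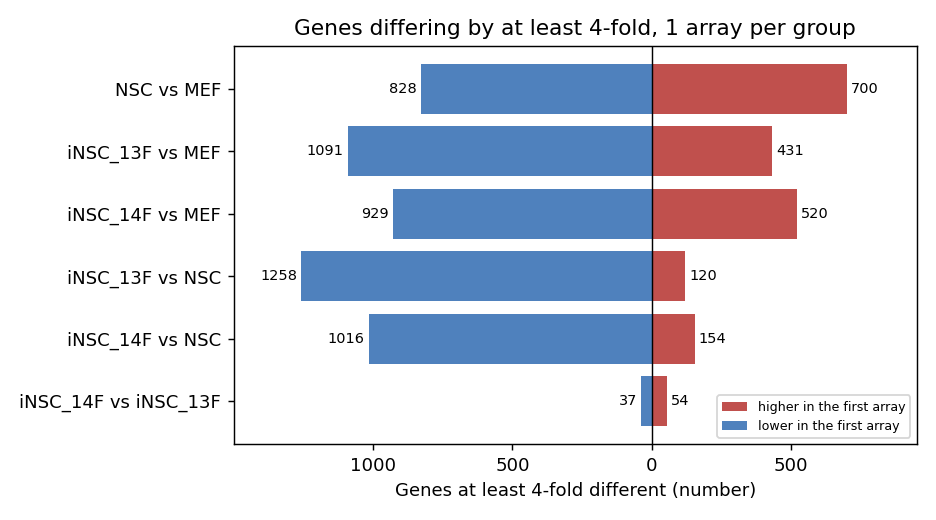
Number of genes at least 4-fold higher (red, to the right) or lower (blue, to the left) in the array named first, for each of the 6 pairs of arrays. The pair of induced arrays differed in 54 and 37 genes, and each other pair in over 1000 genes in all.

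Each gene that separated the references by at least 4-fold was then placed by its level on the induced arrays. Genes higher in MEF were more often at the NSC level than genes higher in NSC were, a comparison in which arrays that are both below the floor count as equal. Of the 828 genes higher in MEF, 68.2% were within 2-fold of NSC on iNSC_13F and 66.8% on iNSC_14F, and 462 were so on both arrays. On both arrays 41 of them were within 2-fold of MEF, and these held Hoxb2 (signals of 862 in MEF, 42.3 in NSC, 933 in iNSC_13F and 865 in iNSC_14F). Of the 700 genes higher in NSC, 33.6% were within 2-fold of NSC on iNSC_13F and 35.3% on iNSC_14F, and 192 were so on both arrays. Olig1, Fabp7, Bex2 and Rfx4 were among them. The signal of Rfx4, a transcription factor of the neural lineage, was 4.36 in MEF, 12110 in NSC, 11681 in iNSC_13F and 10675 in iNSC_14F. Within 2-fold of MEF lay 39.4% of the NSC genes on iNSC_13F and 38.6% on iNSC_14F, 224 of them on both arrays. Ednrb, the endothelin receptor B gene, had a signal of 5003 in NSC, 87.0 in iNSC_13F and 140 in iNSC_14F. Gria2, a glutamate receptor subunit gene, had a signal of 2952 in NSC and was below the floor on both induced arrays. In simulations where an induced array equalled NSC, 93.9% of the NSC genes and 94.1% of the MEF genes came within 2-fold of NSC, and 1.39% and 2.28% did where it equalled MEF. These simulations added noise alone and no offset between arrays. They therefore do not cover a difference such as that in the controls of the NSC array. Over genes above the floor on all 4 arrays, the shares at the NSC level were nearer to each other, at 51.1% and 48.4% of 397 genes higher in MEF and 36.8% and 40.9% of 345 genes higher in NSC. With scaling to hybridization controls, 19.1% and 24.4% of the 700 NSC genes were at the NSC level, and 18.4% and 24.7% of the 2043 genes called higher in NSC under that scaling. With the median of a gene's probe sets, 47.9% and 47.3% of the 700 NSC genes were at the NSC level. That count keeps genes that no longer differed 4-fold between NSC and MEF. Of the 447 genes called higher in NSC under that setting, 34.7% and 35.3% were at the NSC level.

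**Figure D2:**
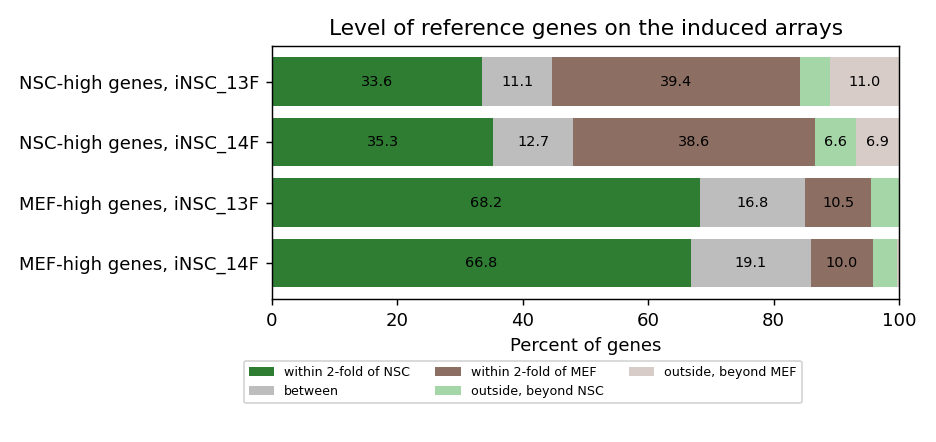
Percent of the 700 genes higher in NSC and of the 828 genes higher in MEF whose level on each induced array was within 2-fold of NSC, within 2-fold of MEF, between them, or outside them. About equal shares of the NSC genes (33.6% and 39.4% on iNSC_13F) lay near NSC and near MEF, whereas 68.2% of the MEF genes lay near NSC. With scaling to hybridization controls 19.1% of the 700 genes were near NSC on iNSC_13F, and with the median of a gene's probe sets 47.9% were. Of the 447 genes called higher in NSC under the latter setting, 34.7% were near NSC on iNSC_13F.

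The induced arrays were compared with NSC to ask in what they differed from the reference neural stem cells. The hybridization controls were about 2-fold lower on the NSC array, so that the direction of several list medians depended on the scaling. The glycolysis and hypoxia list kept its direction in iNSC_14F, with 14 of 16 members at least 2-fold higher. Its median there was 2.69, and 1.755 with scaling to these controls. In iNSC_13F its median of 0.765 turned to -0.309. The median of all genes was 0.30 (log2) for iNSC_13F and 0.33 for iNSC_14F, and it was -0.65 and -0.51 when arrays were scaled to these controls. Neural stem cell and radial glia genes had medians of 0.01 and 0.08, at percentiles 2.33 and 3.98 of matched random lists, whose medians were 0.46 and 0.43. The list medians were -1.03 and -0.85 under that scaling, and that of iNSC_13F was -0.30 with quantile normalization. Of 28 members, 4 were at least 2-fold higher and 7 lower in iNSC_13F, and 5 and 5 in iNSC_14F. Egfr, the receptor of the growth factor in the culture medium, was 5.29-fold and 5.32-fold lower, with 2 of its 3 probe sets in that direction, but its log2 differences were 0.12 and 0.35 with the median of these probe sets. Sox1 was at least 5.05-fold lower on both arrays. The anterior Hox genes, paralog groups 1 to 5, were higher than in NSC for 5 of 6 measured members on each array, with medians of 2.79 and 3.00. These rest on bounds for 5 of the 6 members, which were below the floor on the NSC array. Hoxa3 was at least 9.19-fold and at least 12.0-fold higher. Hoxa5, the member above the floor on both arrays, was 6.28-fold and 7.69-fold higher, and its log2 differences of 2.65 and 2.94 were 1.58 and 2.01 with scaling to the controls. Against MEF the list went both ways, with 2 of 9 measured members at least 2-fold higher and 3 lower in iNSC_13F, and 2 and 3 of 10 in iNSC_14F. Hoxa3 was 6.52-fold and 8.53-fold and Hoxa2 5.12-fold and 5.76-fold higher, and Hoxc5 was at least 3.64-fold lower on both. The forebrain list had medians of -0.33 and -0.43 against NSC, which were -1.24 and -1.35 with scaling to the controls, and Six3 was 2.09-fold lower in iNSC_13F and at least 2.28-fold lower in iNSC_14F. Of the midbrain and hindbrain list 2 members were measured in each comparison with NSC. Gbx2 was at least 2.60-fold higher in iNSC_13F and En2 at least 1.37-fold higher in iNSC_14F. Egr2 was 1.47-fold lower in iNSC_13F and 1.07-fold higher in iNSC_14F, each with 1 of its 2 probe sets in that direction.

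Single genes with the largest differences from NSC included growth factor and transcription factor genes. In iNSC_13F Tcim was 24.2-fold, Hbegf, an EGF receptor ligand, 18.5-fold and Irx5 11.9-fold higher, and Twist1 was at least 11.9-fold higher. Twist1 belongs to the fibroblast and mesenchyme list. Of that list 8 of 24 measured members were at least 2-fold higher and 3 lower in iNSC_13F. In iNSC_14F 7 of 18 were higher and 1 lower, and 13 and 7 members were bounds. The list's medians of 0.42 and 0.57 were -0.08 and 0.10 with scaling to hybridization controls. In iNSC_14F the glucose transporter gene Slc2a3 was 28.6-fold and Bnip3 21.0-fold higher, and Irx5 was 11.7-fold higher. The condensin subunit gene Smc2 was 55.9-fold lower in iNSC_13F and 28.8-fold lower in iNSC_14F. Ednrb was at least 48.1-fold lower in iNSC_13F and 35.7-fold lower in iNSC_14F. Of the neuronal genes 5 of 13 were lower than in NSC and 1 higher in iNSC_13F, and 6 of 9 were lower and 0 higher in iNSC_14F. Gap43 was lower by 6.67-fold and 10.5-fold and Map2 by 8.27-fold and 4.36-fold. The medians of that list were 0.20 in iNSC_13F and -1.42 in iNSC_14F, at percentiles 46.7 and 0.060 of matched random lists. With scaling to hybridization controls they were -0.70 and -1.07, with quantile normalization 0.11 and -0.75, with the median of probe sets -0.22 and -0.80, and over genes above the floor on both arrays -1.76 and -2.13. With the floor at the 99th percentile both were -1.05. Of the astrocyte genes 1 of 10 was at least 2-fold higher and 3 were lower in iNSC_13F, and 1 of 9 was higher and 2 were lower in iNSC_14F. Aldoc was higher by 3.81-fold and 6.26-fold and Sparcl1 lower by 4.84-fold and 6.36-fold. The astrocyte medians of 0.17 and 0.30 were -0.84 and -0.64 with scaling to hybridization controls. Of the oligodendrocyte genes Ugt8a was at least 7.88-fold and Pdgfra at least 5.67-fold lower on both arrays. At 4-fold 120 genes were higher and 1258 lower in iNSC_13F, and 154 were higher and 1016 lower in iNSC_14F. Scaling to hybridization controls gave 34 higher and 2358 lower for iNSC_13F, and 38 and 2000 for iNSC_14F. With no floor 320 and 255 were higher. With the median of a gene's probe sets in place of the brightest, 710 and 592 were lower. Both comparisons share the NSC array. They had 45 genes higher and 948 lower in common, where independent lists would share 1.76 and 122 and simulated arrays with no effect 13.5, and part of this excess may come from that array. The covariance was 1.47, against 0.139 simulated.

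Genes at least 4-fold apart from both references on both induced arrays were mostly lower ones, with 13 higher and 248 lower. Tmed5, which codes for a transport protein of the secretory pathway, had signals of 1991 in MEF, 3741 in NSC, 89.5 in iNSC_13F and 88.3 in iNSC_14F. Grb10, an imprinted gene for an adaptor of the insulin receptor, had 16466, 2623, 57.9 and 173. Eif2s2, a subunit of a translation initiation factor, had 13959, 13289, 813 and 1038, and Mbnl1, a splicing regulator, had 6034, 4491, 336 and 358. Far1, Exoc5, Erbin and Pik3c2a were lower by 13.9-fold, 11.6-fold, 10.5-fold and 10.2-fold or more in each of the 4 comparisons. Among the 13 higher genes, Hoxa3 had signals of 146 in MEF, 7.36 in NSC, 954 in iNSC_13F and 1249 in iNSC_14F. Nptx1, a neuronal pentraxin gene, had 2.47, 1801, 12252 and 9732. With the median of a gene's probe sets the counts were 7 higher and 98 lower. The number higher was 21 with quantile normalization and 3 with scaling to hybridization controls. Over genes above the floor on all 4 arrays they were 1 and 136.

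The 2 induced samples were compared with each other, as cells made with 14 and with 13 factors, whose starting cells are not given and may also differ. Genes of glycolysis and the response to low oxygen were higher in iNSC_14F. Of 16 measured members of the list, 13 were at least 2-fold higher and 0 lower, with a median log2 difference of 1.82, which was 1.70 with quantile normalization and 1.96 with scaling to hybridization controls. No list in 10000 random ones matched on size and expression had a higher median. Bnip3, a mitochondrial protein gene induced by low oxygen, was 21.9-fold higher, and Egln3, an oxygen-sensing hydroxylase gene, was 14.0-fold higher. Ankrd37 was 13.1-fold and Pdk1 10.1-fold higher. Outside the list, Slc2a3 was 24.4-fold, Ppp1r3c 13.8-fold and Ddit4 8.51-fold higher. Notch pathway genes were at least 2-fold higher for 6 of 12 members and lower for 0, with a median of 0.95. Among them Hes5, a Notch target, was at least 10.4-fold higher and Hey1 2.40-fold higher. Mest, an imprinted gene with 1 probe set here, was 42.3-fold lower in iNSC_14F. Hbegf was 19.7-fold, Nmral1 14.3-fold, Dmp1 10.4-fold and Sgk1 9.88-fold lower. The ERK feedback list had a median of -0.43 (-0.29 with scaling to hybridization controls), with 3 of 12 lower and 1 higher, and Spry4 was 4.12-fold lower. Twist1 and Ccn2 were at least 11.9-fold and at least 10.3-fold lower. Igfbp5 was 7.62-fold higher, but its log2 difference was -0.70 when shared probe sets were left out. In all 54 genes were at least 4-fold higher in iNSC_14F and 37 lower. Of these calls 59.3% were higher, against 50.5% with quantile normalization and 71.4% with scaling to hybridization controls, under which the median of all genes moved from 0.07 to 0.21. The same rule called 36.65 unchanged genes on average in simulated arrays with the noise of this pair, so part of the calls may be noise. With no floor the balance turned, to 115 higher and 174 lower.

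**Figure D3:**
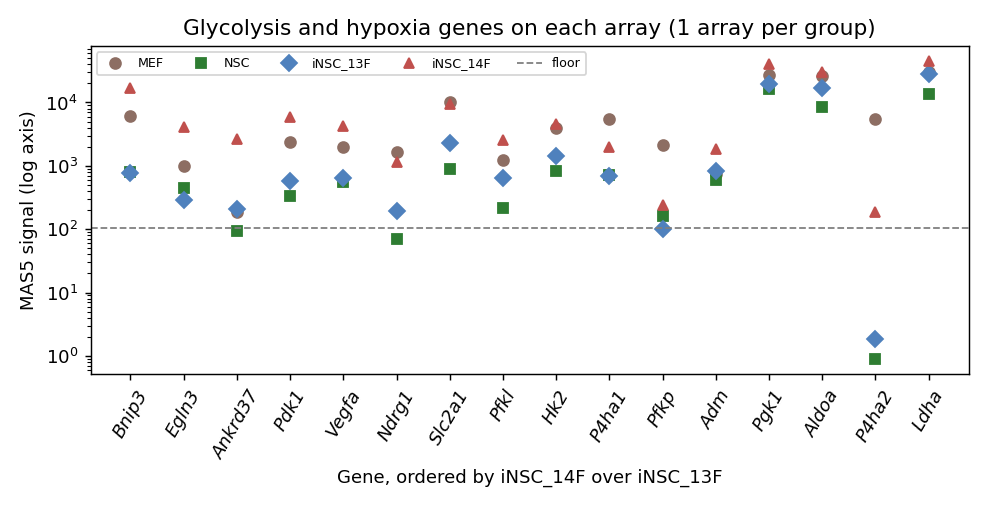
MAS5 signal (log axis) of the 16 measured genes of the glycolysis and hypoxia list on each of the 4 arrays, with the floor of 103.91 as a dashed line. Genes are ordered by the ratio of iNSC_14F to iNSC_13F, and Bnip3, at 21.9-fold, is the first.

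Factor genes and genes of other cell types were read on each array. The factor list holds a set of 8 taken from general knowledge of the publication of the study. The labels do not say which factors make up the 13 and the 14, so these 8 may not be those the samples received, and the probe sets do not tell introduced from resident copies. Rfx4 was at the NSC level on both induced arrays. Myc had signals of 3046 in MEF, 2572 in NSC, 8335 in iNSC_13F and 4049 in iNSC_14F. Klf4 had 4472, 435, 2264 and 1706, and Notch1 had 1517, 1232, 2313 and 6455. Plagl1 had 5120, 662, 498 and 196, and Hes1 had 1005, 961, 780 and 1825. Pou3f2 was above the floor in iNSC_14F alone, at 146, and Hes3 was below it on all 4 arrays. Of the hepatocyte list 1 gene was measured, Apoa2, which was at least 1.20-fold lower on both induced arrays than in MEF. Of the B lymphocyte list at most 4 genes were measured in a comparison. Against MEF, Igll1 and Cd74 were higher in iNSC_13F by at least 2.03-fold and at least 1.86-fold, and Ebf1 was 2.80-fold lower in iNSC_14F. Pluripotency genes were at most 7 in a comparison. Against MEF, Tbx3 was at least 6.60-fold lower on both induced arrays and Esrrb at least 2.46-fold higher in iNSC_13F. Of endothelial genes Plvap was at least 33.8-fold and at least 33.5-fold higher than in MEF, and it was 2.82-fold and 2.79-fold higher than in NSC. Of neural crest genes Tfap2a had log2 differences of 1.05 and 2.81 from MEF. Acta1, of the muscle list, was 17.6-fold and at least 25.3-fold lower, and Krt18, of the epithelial list, at least 5.62-fold lower on both. The macrophage gene Csf1r was 1.62-fold and 1.34-fold lower, and Asz1, the measured gene of the germline list, 1.22-fold and 1.10-fold lower. Of at most 4 Hedgehog genes measured against MEF the medians were -0.72 and -0.14. The former was -1.65 with scaling to hybridization controls and the latter 0.05 with quantile normalization. Ptch1 was higher by 2.03-fold and 3.80-fold. Housekeeping genes had medians of 0.10 and 0.14 against MEF, the former -0.05 with quantile normalization and -0.06 with scaling to hybridization controls. Against NSC their medians were 0.54 and 0.72, which became 0.01 and -0.11 with quantile normalization and -0.53 and -0.22 with scaling to these controls.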

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

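Results were singled out here where iNSC_13F and iNSC_14F lay on opposite sides of the same reference, by at least 0.5 (log2) for a list median over 5 or more members and by at least 1 for a gene above the floor on both arrays of each comparison. These limits, and the tests of scaling and of culture, were chosen after the data were seen. The list of further hypoxia genes was written before its values were looked at, although the pattern it tests was known. With 1 array per group the differences between the induced samples were not tested.

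Against MEF, the glycolysis and hypoxia list had a median log2 difference of -1.71 in iNSC_13F and 0.59 in iNSC_14F. Its members Bnip3 (-3.00 and 1.45), Egln3 (-1.78 and 2.03), Pdk1 (-2.08 and 1.26) and Vegfa (-1.63 and 1.07) were below MEF in iNSC_13F and above it in iNSC_14F. Outside that list, the glucose transporter gene Slc2a3 had -1.15 and 3.45, the glycogen synthase gene Gys1 -1.04 and 1.24, and Btg2 -1.52 and 1.19. Nmral1 went the other way, at 1.95 in iNSC_13F and -1.89 in iNSC_14F. With quantile normalization the list median in iNSC_14F was 0.32, and the values of Gys1 and Slc2a3 in iNSC_13F were -0.80 and -0.99. With the median of a gene's probe sets the list median in iNSC_13F was -1.15, and 1 or both values fell below 1 in size for Gys1 (-0.52 and 0.62), Slc2a3 (-0.47 and 1.67), Vegfa (-1.68 and 0.63), Egln3 (-0.89 and 2.44) and Btg2 (-1.42 and 0.95).

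Against NSC, Ccng2 had a log2 difference of -1.29 in iNSC_13F and 1.51 in iNSC_14F, Myorg -1.35 and 1.06, and Usp2 -1.02 and 1.13. Pou3f1, a POU-domain transcription factor gene, had 1.23 and -1.57, and Rgs2 had 1.37 and -1.11. With scaling to hybridization controls none of these 5 genes lay at least 1 above NSC, the higher values being 0.58 (Ccng2), 0.12 (Myorg), 0.19 (Usp2), 0.16 (Pou3f1) and 0.29 (Rgs2). Other settings brought the lower value of 3 of them nearer to 0 than -1. That of Usp2 was -0.67 with quantile normalization, -0.84 with the median of probe sets and -0.98 with no floor, that of Rgs2 was -0.84 and -0.80 with the first 2 of these, and that of Myorg was -0.64 with the floor at the 99th percentile.

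The higher level of hypoxia and glycolysis genes in iNSC_14F than in iNSC_13F was weighed against technical causes. Array scaling as the cause is argued against by the list's median, which was 1.70 under quantile normalization, against 1.82 in the deposited scaling. A wider hypoxia response is a candidate explanation, since another list of 25 such genes had a median of 1.30, at percentile 100 of matched random lists, with 13 of 22 measured members at least 2-fold higher and 0 lower, led by Gys1 (4.84-fold) and Ero1a (4.41-fold). Culture conditions at harvest, such as cell density, cannot be told apart from the number of factors, because each group has 1 array. The same holds for the starting cells, which the labels do not give. Xist was above the floor in iNSC_13F and below it in iNSC_14F, so these cells may differ. An effect of the factors stays open and untested.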

How the results depend on the processing

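Scaling to hybridization controls, leaving out a reference array and following the main 700 genes under another setting were chosen after the data were seen. The cause of a change was not tested, except where an alternative by construction counts fewer genes (genes above the floor on both arrays) or drops a condition (a reference array left out). No paired analysis was possible because each group has 1 array. The deposited values without rescaling give the same values as the main ones, since their trimmed means are equal, and have no result of their own. Signal over background limits all bounds, whose size is set by the floor. A list median or gene counted as reversed where its sign changed from a difference of at least 2-fold, and a difference of r where its sign changed. Tolerances were 1.5 times for counts, the SD of random lists for list medians, the 95% Wilson interval of the share for percents and 0.0243 for differences of r. Of the values of main results under the alternatives, 128 stayed within them, 91 moved beyond and 1 reversed. For other list medians these numbers were 947, 311 and 5. Of all 1319 list medians under the alternatives 103 changed sign, 42 of them with scaling to hybridization controls. For named genes, with the pooled SD of a gene's probe sets as the tolerance, they were 4516, 1112 and 7. Percents at the NSC level below are of the genes called under each setting.

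With quantile normalization, genes at least 4-fold higher in iNSC_13F than NSC were 194, and the genes higher in both induced arrays than in both references 21. MEF-high genes at the NSC level were 61.2% on iNSC_13F and 60.7% on iNSC_14F. The neural stem cell list median for iNSC_13F against NSC was -0.30.

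With the floor at the 75th percentile, genes higher than in NSC were 189 in iNSC_13F and 241 in iNSC_14F, genes lower in iNSC_14F than iNSC_13F 65, and genes higher than in both references 21. MEF-high genes at the NSC level were 61.4% and 63.4%. The fibroblast list median for NSC against MEF was -6.70. These list medians reversed: the oligodendrocyte list for NSC against MEF (-0.078, from 1.66), the skeletal muscle list for iNSC_13F against MEF (0.22, from -2.27) and the Wnt response list for iNSC_14F against MEF (-0.18, from 1.21). With the floor at the 99th percentile, MEF-high genes at the NSC level were 70.2% on iNSC_14F. The neural stem cell list median for NSC against MEF was 2.96, and the fibroblast list medians against MEF were -5.61 (NSC), -5.10 (iNSC_13F) and -5.26 (iNSC_14F).

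With no floor and a pseudocount of 16, r with NSC minus r with MEF was 0.072 for iNSC_13F and 0.112 for iNSC_14F. Genes higher in iNSC_13F than MEF were 680, higher than in NSC 320 (iNSC_13F) and 255 (iNSC_14F), and between the induced arrays 115 were higher and 174 lower in iNSC_14F. Genes higher than in both references were 22. NSC-high genes at the NSC level were 38.1% on iNSC_13F, and MEF-high genes 51.1% and 55.6%. The fibroblast list medians were -6.93 (NSC against MEF) and -6.25 (iNSC_14F against MEF), and the glycolysis and hypoxia median between the induced arrays was 1.98. Pdgfra for NSC against MEF reversed to -0.65, from 1.40.

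With the median of a gene's probe sets, 447 genes were higher in NSC than MEF. Against MEF 680 were lower in iNSC_13F, and 333 were higher and 608 lower in iNSC_14F. Against NSC 710 were lower in iNSC_13F, and 92 were higher and 592 lower in iNSC_14F. Between the induced arrays 19 were lower in iNSC_14F. Genes apart from both references were 7 higher and 98 lower. MEF-high genes at the NSC level were 73.9% and 72.2%. List medians were 3.04 (neural stem cell list, NSC against MEF), -5.15, -5.00 and -4.99 (fibroblast list, NSC, iNSC_13F and iNSC_14F against MEF) and 1.30 (glycolysis and hypoxia, between the induced arrays). Egfr reversed for NSC against MEF (-0.23, from 1.88), iNSC_13F against NSC (0.12, from -2.40) and iNSC_14F against NSC (0.35, from -2.41), and Pdgfra for NSC against MEF (-0.72, from 1.40). Without _s_at and _x_at probe sets, the fibroblast medians were -5.24 (iNSC_13F) and -5.11 (iNSC_14F), the glycolysis and hypoxia median was 1.67, and Igfbp5 between the induced arrays reversed to -0.70, from 2.93.

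With genes above the floor on both arrays, the nearness of iNSC_13F to NSC in r reversed to -0.0191, and that of iNSC_14F was 0.0057. Genes higher and lower in NSC than MEF were 426 and 456, in iNSC_13F than MEF 240 and 640, in iNSC_14F than MEF 287 and 513, and in iNSC_13F than NSC 79 and 838. Between the induced arrays 23 were lower in iNSC_14F. Genes apart from both references were 1 higher and 136 lower. NSC-high genes at the NSC level were 40.9% on iNSC_14F, and MEF-high genes 51.1% and 48.4%. List medians were 2.57 (neural stem cell list, NSC against MEF), -3.96, -5.31 and -4.64 (fibroblast list, NSC, iNSC_13F and iNSC_14F against MEF) and 2.00 (glycolysis and hypoxia).

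With scaling to hybridization controls, genes higher and lower in NSC than MEF were 2043 and 530, in iNSC_13F than NSC 34 and 2358, and in iNSC_14F than NSC 38 and 2000. Genes higher than in both references were 3. Of the NSC-high genes 18.4% and 24.7% were at the NSC level (19.1% and 24.4% of the main 700), and MEF-high genes 77.4% and 80.0%. The neural stem cell list medians were 4.39 (NSC against MEF), -1.03 (iNSC_13F against NSC) and -0.85 (iNSC_14F against NSC), the fibroblast median for NSC against MEF -5.83, and the glycolysis and hypoxia median between the induced arrays 1.96. The endothelial list against NSC reversed to -0.24 (iNSC_13F) and -0.14 (iNSC_14F), and so did Fgfr3 for iNSC_13F against NSC (-0.042, from 1.03). Without the NSC array, 322 genes were higher and 826 lower in both induced arrays than in MEF, and without the MEF array 45 were higher and 948 lower than in NSC.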

Other observations

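The tests of the genes lower in both induced samples and of Xist were chosen after these results were seen, and the test of the neighbour trend as the whole cause was added when the neighbour correlation was known. Imprinted genes differed widely between the arrays. Against MEF, 8 of 16 measured members were at least 2-fold lower and 2 higher in iNSC_13F (median log2 difference -1.23), and 7 of 17 were lower and 0 higher in iNSC_14F (-0.98). Igf2, a growth factor gene, was at least 124-fold lower on both arrays, and Meg3, a non-coding RNA, was at least 93.5-fold lower in iNSC_13F and 65.6-fold lower in iNSC_14F. In NSC they were at least 124-fold and at least 93.5-fold lower. Grb10 was at least 25.2-fold lower in iNSC_13F and 15.1-fold lower in iNSC_14F than in NSC, and Nnat at least 13.8-fold lower on both. Mest was 26.9-fold higher in NSC and 26.8-fold higher in iNSC_13F than in MEF, and 42.5-fold lower in iNSC_14F than in NSC. Genes of the MHC class I pathway had medians against MEF of -0.63 in iNSC_13F and -0.27 in iNSC_14F, with B2m lower by 4.23-fold and 4.64-fold. The interferon response list had a median of -0.59 on both, and Irgm1 was 4.33-fold and at least 6.06-fold lower.

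Cell cycle and p53 genes differed from NSC in both directions. Of 32 cell cycle genes 8 were at least 2-fold lower and 3 higher on each induced array, with medians of 0.48 and 0.36 that were -0.59 and -0.57 with scaling to hybridization controls. A few members were far lower than in NSC, among them Mki67, a gene read as a mark of proliferation (32.1-fold in iNSC_13F), Ccne2 (25.6-fold and 21.9-fold) and Bub1 (at least 35.9-fold and 20.7-fold). Of 17 genes of the p53 response and senescence, 5 were at least 2-fold lower on each induced array, and 2 were higher in iNSC_13F and 3 in iNSC_14F. The medians of -0.23 and 0.02 were -1.30 and -0.92 with scaling to hybridization controls. Ccng1 was lower by 42.5-fold and 9.91-fold and Trp53inp1 by 39.2-fold and 6.70-fold. The 3 probe sets of Ccng1 had log2 differences from -5.41 to -1.08 in iNSC_13F. Between the induced samples 5 of 16 genes of that list were higher and 0 lower in iNSC_14F (median 0.73). Trp53inp1 was 5.85-fold and Bbc3 3.61-fold higher.

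For the 248 genes lower in both induced samples than in MEF and NSC, array scaling as the cause is argued against by the 209 such genes under quantile normalization. Probe placement is argued against as the cause for 160 of them, whose 301 other probe sets had a median smallest log2 difference of -1.54 (0.57 for other probe sets of all genes), although 70.1% of these were 2-fold and 31.2% 4-fold lower, and 98 genes were left with the median of probe sets. It cannot be told apart from a change of the gene for the other 88, which have no other probe set above the floor in MEF and NSC. A trend shared by neighbouring genes may take part, since neighbours in the annotation correlated at 0.214, against 0.041 between the induced arrays. The correlation was 0.264 in the comparison with NSC, whose controls stood apart, and 0.0933 with MEF. Between NSC and MEF, without an induced array, it was 0.0855, so the value with MEF lay little above that of the references. After the median of 10 neighbours on either side, the only window tried, was subtracted, 102 of 135 genes (75.6%) stayed 4-fold lower. These were counted over the 8147 genes above the floor on all arrays that the annotation places. The correction averaged 0.441 (log2) in size, too little to take away most 4-fold differences, so the share that stayed follows from that size. Counted anew, 142 genes were 4-fold lower after it. The median smallest difference of the 135 genes was -2.37 before and -2.29 after, so their neighbours shared little of the drop. This argues against a trend shared evenly by neighbours as the whole cause, but not against a technical cause that differs between neighbours. GC content was not analysed here, RNA degradation was not decided by the 3' to 5' ratios, and a biological difference stays open and untested.

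Xist, the RNA that coats the inactive X chromosome, had signals of 2893 in MEF, 13134 in NSC, 3072 in iNSC_13F and 58.0 in iNSC_14F, the last below the floor. A candidate explanation is that the iNSC_14F cells came from a male. Of 2 Y-linked genes above the floor on any array, 1 was at least 2-fold higher in iNSC_14F than in iNSC_13F. Eif2s3y had signals of 367 in MEF, 106 in iNSC_13F and 408 in iNSC_14F and was below the floor in NSC, Uty was above the floor in MEF alone, at 123, and Kdm5d on no array. Male cells and loss of Xist from female cells cannot be told apart with 2 such genes, and a loss was not tested.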
